A study of Homo sapiens with 12 samples.

How the data were processed

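RNA was sequenced from 4 human glioblastoma cell lines with 3 libraries each, 12 in all: the parental lines U251MG and U87MG, and U251TR and U87TR, derived from them by repeated exposure to rising temozolomide. According to the labels, libraries were made with the TruSeq kit from RNA with an integrity number of at least 6.8, had a median insert of 200 nucleotides, and were read as 150 bp pairs on an Illumina HiSeq. The submitters' processing notes name STAR 2.5.2b and RSEM 1.2.31. Those notes give the build as hg19 while the design text gives hg38. The symbols in the table are of the hg19 era, and no coordinate is printed.

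The deposited table holds FPKM to 2 decimals, by gene symbol, for 31681 symbol rows. No header or label states that unit. It was inferred from the values, which sum to between 696371 and 786642 per library, and from the sum of value times gene length, which came to 1.01 to 1.06 times what FPKM would give if every fragment were counted in a matched gene. The table holds no counts, so no counting interval is given. Symbols turned into dates by a spreadsheet (27 of them) were left out because they no longer name a gene. The other symbols were matched to the gene table of assembly GRCh38.p14 for chromosome and neighbour order. Of 31679 distinct symbols, the date names included, 21557 were matched.

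Genes at 1 FPKM or more in at least 3 libraries were tested, which left 15449. A group-means model was fitted to log2(FPKM + 1) of all 12 libraries in limma 3.58.1 (R 4.3.3), with a trend of the variance on expression and robust moderation. Adjusted p-values are Benjamini-Hochberg over the genes tested in a comparison, from two-sided tests, with a threshold of 0.05. Fold changes and their standard errors (SE) come from this scale, where the added 1 FPKM shrinks the fold of weakly expressed genes. Levels are group means with the standard deviation (SD) between libraries. For a gene listed at 0 in every library of a group, values are given instead of a fold, except that a difference between the lines is given on the log2(FPKM + 1) scale. The comparisons were U251TR against U251MG, U87TR against U87MG, the difference between those changes, their overlap, and U87MG against U251MG. The library codes of U87TR come from another number block than those of the other 9 libraries, so block and resistance are the same split in the U87 comparison.

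Before the data were examined, 36 gene lists were fixed from general knowledge, as were the rules for named genes, the threshold and the other settings of the fit. Lists were tested against all other genes with camera at a preset correlation between genes of 0.01, adjusted over the 36 lists in a comparison. Camera with an estimated correlation was the other setting of this test. Fry was run beside it and answers another question, whether a list changed at all, not whether it changed more than other genes. Named genes were 14 fixed genes of DNA repair and ferroptosis, the 6 largest rises and falls per resistance comparison, and the 6 largest in each direction in both lines. They also include the 4 largest opposite changes per direction, the 5 largest parental differences per direction, and up to 4 members of a list with the largest changes. Genes named for the size of their change had a plain gene symbol (no clone, antisense or pseudogene name) and at least 10 FPKM in the higher group, and the largest rises and falls had no overlap between the 2 groups' libraries. Some of the genes and gene runs found by these rules are not reported here. Any other gene named was chosen after its values were seen.

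Line identity was checked with genes at 10 or more FPKM in every library of one parent and under 0.1 in every library of the other. A gene counted as kept at over 1 FPKM. Chromosome medians were set against 10000 random gene sets of the same size. A scan of 15 neighbouring genes at a time was added after the data were seen, with a limit from 1000 shuffles of gene order. The fit was tested on simulated data with each gene's parental mean and fitted spread, normal noise, and 200 genes changed per line. The changed genes were drawn only from those above 10 FPKM on average (log scale) in both parents. Recovery of more weakly expressed genes was not tested. Of genes changed 1.5-, 2- and 4-fold in U251, 79.1%, 92.5% and 100% were recovered, and 8 unchanged genes were called. In U87 these were 76.1%, 98.5% and 100% with 16 unchanged genes called, and for the difference 48.5%, 88.8% and 100% with 18. Noise was drawn independently for each gene, and far fewer genes were changed than the 8222 and 4294 called in U251TR and U87TR. The rates of recovery and of unchanged genes called may therefore not hold in the data.

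The other settings were pseudocounts of 0.1 and 5, no filter, a filter at 5 FPKM (fixed as 5 CPM before the unit was known), at least 2-fold calls, a replicate block, a fit on the 6 libraries of a comparison alone, and leaving out each library in turn. Another 3 scalings were added after the data were seen: median-of-ratios factors, rescaling each library to TPM, and quantile normalization.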

Results

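The data were gene expression values (FPKM) from 12 RNA sequencing libraries, 3 from each of 4 human glioblastoma lines. U251MG and U87MG are long-established glioblastoma lines. U251TR and U87TR are their derivatives, kept under rising concentrations of temozolomide, an alkylating drug given to glioblastoma patients, until they tolerated it. The libraries had between 13135 and 14122 genes at 1 FPKM or more, and 15449 genes were tested. The labels do not say whether the 3 libraries of a line came from separate cultures, so the p-values measure only the spread between these libraries. Each parent had only 1 resistant line. In both lines, resistance therefore cannot be told apart from other changes that arose while the resistant line was derived.

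Cell line was the largest source of variation. The first principal component held 73.5% of the variance and separated the 6 U251 libraries from the 6 U87 libraries. The second held 14.1% and separated U251TR from U251MG, and the third held 6.27% and separated U87TR from U87MG. Each resistant line kept the genes of its named parent. U87TR had 98.0% ± 1.4 (SD, n = 3) of 81 U87MG genes still on and 0% of 55 U251MG genes. U251TR had 84.9% ± 1.1 (SD, n = 3) of the 55 U251MG genes still on and 3.7% ± 0 (SD, n = 3) of the 81 U87MG genes. U251MG replicate 2 stood apart from the other libraries of its line, with rank correlations across genes of 0.977 and 0.978 against 0.993 between replicates 1 and 3. U87MG replicate 3 did so to a lesser degree, with 0.983 and 0.987 against 0.993 between replicates 1 and 2.

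The first comparison asked what set U251TR apart from its parent U251MG. The gene with the largest rise was CHI3L1, which codes for a secreted glycoprotein of mesenchymal glioblastoma. It went from 2.01 ± 0.358 to 2637 ± 455 FPKM (SD, n = 3), a log2 fold change of 9.77 (SE 0.13, adjusted p = 6.53e-13). The chemokine gene CCL5 rose from 0.0233 ± 0.0252 to 106.5 ± 16.1 FPKM (SD, n = 3). MGMT, which codes for the enzyme that removes the methyl group temozolomide leaves on guanine, was listed at 0 in all 3 U251MG libraries and stood at 8.73, 7.7 and 9.58 FPKM in the U251TR libraries (adjusted p = 1.37e-10). The chemokine gene CXCL14 fell from 414.9 ± 148 to 5.49 ± 2.74 FPKM (SD, n = 3). ANKRD1, a target gene of the coactivator YAP, fell by 5.7 on the log2 scale (SE 0.11). MSMP, SPARCL1, CADM3 and S100A9 completed the 6 largest rises among genes with a plain symbol, the first of these with a log2 fold change of 7.24. S100A9 was listed at 0 in U251MG and had 65.39 ± 19 FPKM (SD, n = 3) in U251TR. FILIP1L, C6orf15, MT1E and PDE1C completed the 6 largest falls among such genes, with log2 fold changes from -5.89 to -4.49.

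Inflammatory and antigen presentation genes rose together in U251TR. Of 24 interferon-stimulated genes, 22 rose and none fell, with a median log2 fold change of 2.51 (adjusted p = 9.37e-12, and adjusted p = 0.0109 with an estimated correlation). IFIT2, an interferon-induced antiviral gene, rose 34.3-fold and RSAD2, another, rose 25.8-fold. All 11 tested genes of MHC class I presentation rose (adjusted p = 4.06e-06, but adjusted p = 0.289 with an estimated correlation). Among them HLA-B rose 5.06-fold, HLA-F 5.01-fold and PSMB9, a subunit of the immunoproteasome, 3.55-fold. Of 21 NF-kB cytokine and response genes, 14 rose and 1 fell (adjusted p = 0.00284, but adjusted p = 0.443 with an estimated correlation). IL6 rose from 1.78 ± 0.512 to 58.02 ± 6.32 FPKM (SD, n = 3), and CCL2 from 16.91 ± 15.5 to 211.5 ± 9.61 FPKM (SD, n = 3), a log2 fold change of 3.91 that was 4.58 without U251MG replicate 2.

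Antioxidant and mitotic genes were also higher in U251TR, and ribosomal protein genes were lower. Of 23 target genes of NRF2, the regulator of the antioxidant response, 18 rose and none fell (median log2 fold change 1.29, adjusted p = 3.19e-06, but adjusted p = 0.115 with an estimated correlation). AKR1B10 rose 30.6-fold and AKR1C1 rose 24.1-fold; both code for aldo-keto reductases. Of 24 genes of G2 and mitosis, 20 rose and none fell (adjusted p = 0.000363, but adjusted p = 0.624 with an estimated correlation), among them AURKA at 2.41-fold and CCNB2 at 2.23-fold. Of 30 ribosomal protein genes, 25 fell and 1 rose (median log2 fold change -0.57, adjusted p = 3.66e-10, but adjusted p = 0.443 with an estimated correlation). RPS4X fell by 1.37 on the log2 scale and was the only 1 of the 30 to fall by at least 2-fold. Of 19 proneural and neural stem cell genes, 10 fell and 2 rose (adjusted p = 0.000924, but adjusted p = 0.218 with an estimated correlation). PDGFRA fell from 59.96 ± 30.3 to 7.70 ± 0.577 FPKM (SD, n = 3) and NES, the gene of nestin, from 195.6 ± 29.4 to 42.63 ± 2.75 FPKM (SD, n = 3). Of 17 TGF-beta and YAP target genes, 9 fell and 4 rose (adjusted p = 0.00625, but adjusted p = 0.294 with an estimated correlation). CDKN1A, which codes for the cell cycle inhibitor p21, rose 2.69-fold in U251TR and had a log2 fold change of -0.11 (SE 0.16, adjusted p = 0.656) in U87TR. Astrocyte markers moved both ways, with 3 of 9 rising and 4 falling (the same adjusted over the list alone, adjusted p = 0.55). Among them GFAP rose from 22.83 ± 6.19 to 396.2 ± 17.4 FPKM (SD, n = 3), while SLC1A3 and GJA1 fell by 2.37 and 2.21 on the log2 scale. Of 13 mitochondrially encoded transcripts, a sign of RNA quality, 7 fell and none rose (adjusted p = 0.0108, but adjusted p = 0.535 with an estimated correlation, 0.0587 without U251MG replicate 2, and the direction turned under quantile normalization).

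In this comparison 8222 genes changed, 5193 upward and 3029 downward, and 2096 of them by at least 2-fold. Without U251MG replicate 2 the count was 8961. The share of changed genes that were higher depended on scaling: it was 63.2% on the deposited values, 53.6% with median-of-ratios factors, 72.1% after rescaling to TPM and 49.3% after quantile normalization. Of the 36 lists 10 passed, while other splits of these 6 libraries into 3 and 3 passed as many as 13. Those splits mix the real groups and keep part of their difference, so they do not show what chance alone gives. Member counts are given beside each list's p. Adjusted over the list alone, the member counts of these lists were the same except for the ferroptosis suppressors.

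**Figure D1:**
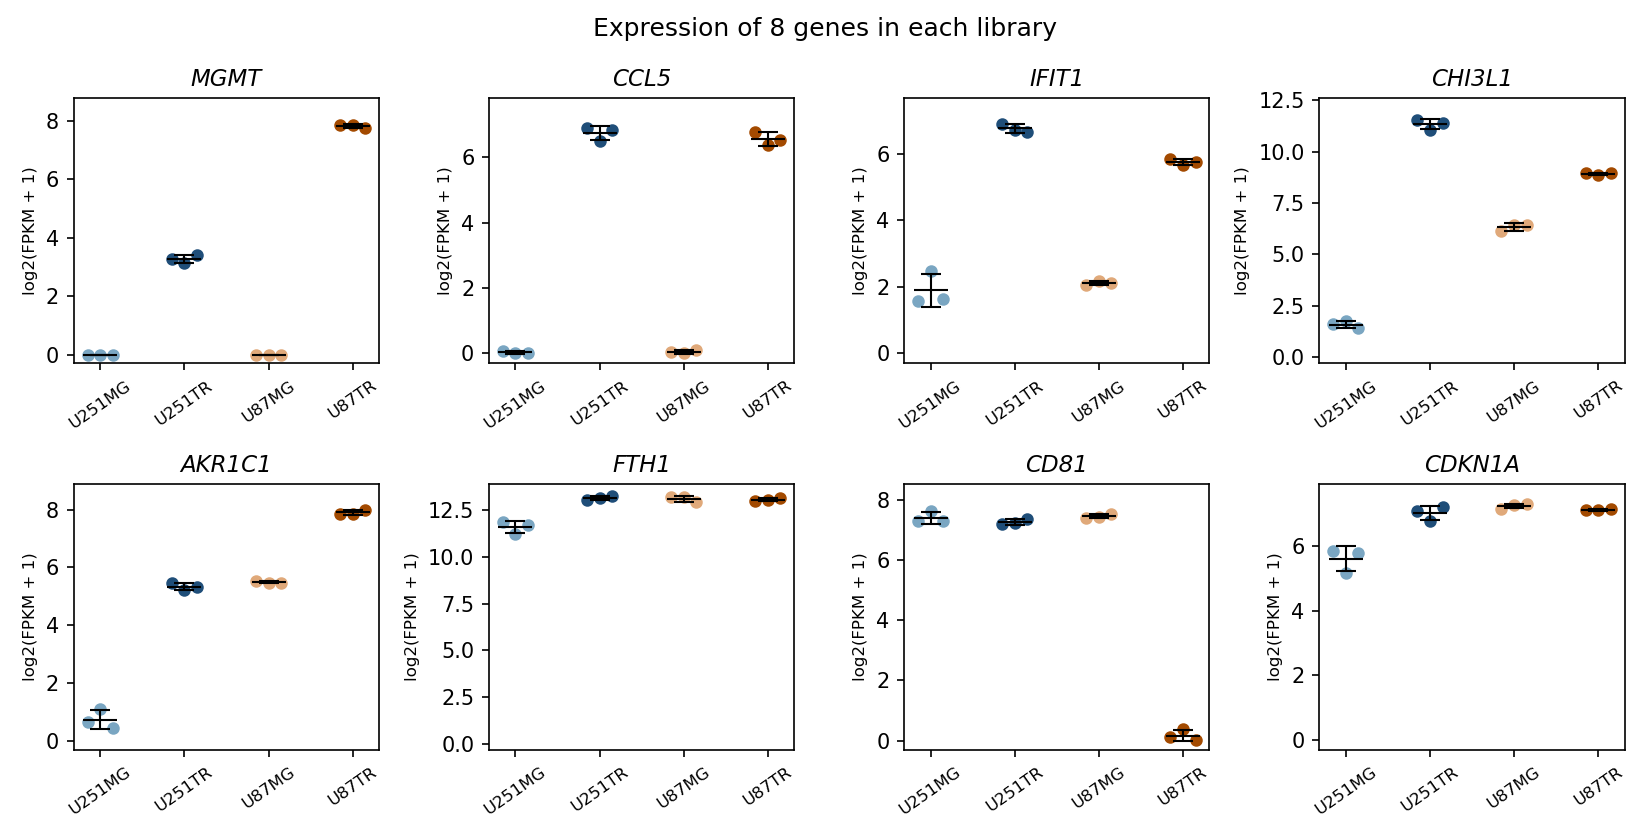
Expression of 8 genes in each of the 12 libraries, as log2(FPKM + 1) on the vertical axis and the cell line on the horizontal axis; points are libraries, and bars are the mean and SD of 3. MGMT and CCL5 were near 0 in both parental lines and on in both resistant lines, and CD81 was at 0.127 ± 0.146 FPKM in U87TR against 173.9 ± 8.02 in U87MG.

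The second comparison asked the same of U87TR and its parent U87MG. MGMT had the largest rise. It was listed at 0 in all 3 U87MG libraries and stood at 232.22, 227.26 and 212.66 FPKM in the U87TR libraries (adjusted p = 1.29e-13). CCL5 rose from 0.0333 ± 0.0351 to 93.85 ± 13.3 FPKM (SD, n = 3). C10orf118, IFIT2, SERPINA1 and MYO15B completed the 6 largest rises among genes with a plain symbol, with log2 fold changes from 3.89 to 4.37. CD81, which codes for a tetraspanin of the cell surface, had the largest fall, by 7.28 on the log2 scale (SE 0.11, adjusted p = 1.73e-12). E2F7, a repressor of E2F target genes, went from 28.29 ± 3.89 to 0.0133 ± 0.0115 FPKM (SD, n = 3). EHD2, MEG3 and ST8SIA5 were listed at 0 in all 3 U87TR libraries, from 67.91 ± 13.5, 22.95 ± 1.79 and 21.8 ± 13.2 FPKM (SD, n = 3) in U87MG. SERPINB2 fell by 4.39 on the log2 scale (SE 0.3).

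Interferon-stimulated genes rose in U87TR as well. Of 24, 13 rose and none fell, with a median log2 fold change of 0.86 (adjusted p = 9.81e-12, and adjusted p = 0.011 with an estimated correlation). Adjusted over the list alone, 15 rose and 1 fell. IFIT2 rose 17.8-fold, RSAD2 13.5-fold and IFIT1 12.5-fold. Of 11 MHC class I presentation genes, 7 rose and none fell (7 adjusted over the list alone; adjusted p = 0.000506, but adjusted p = 0.461 with an estimated correlation). B2M, the light chain of MHC class I, rose from 2941 ± 36.3 to 5246 ± 177 FPKM (SD, n = 3). Of 23 NRF2 target genes, 9 rose and 2 fell (10 and 3 adjusted over the list alone; adjusted p = 0.000158, but adjusted p = 0.244 with an estimated correlation). ABCC2, a drug efflux transporter, rose from 3.46 ± 0.493 to 45.37 ± 5.37 FPKM (SD, n = 3). Of 8 epithelial marker genes, 6 rose and none fell (6 adjusted over the list alone; adjusted p = 3.62e-05, but adjusted p = 0.0798 with an estimated correlation). KRT8 rose from 14.16 ± 3.89 to 34.11 ± 1.15 FPKM (SD, n = 3), while KRT14, ELF3 and CLDN7 stayed under 4 FPKM on average. Of 19 growth factor receptor and MAPK output genes, 9 fell and 1 rose (10 and 1 adjusted over the list alone; adjusted p = 0.0145, but adjusted p = 0.597 with an estimated correlation and 0.0513 without U87MG replicate 3). CCND1 fell from 258.5 ± 16.1 to 132.6 ± 14.3 FPKM (SD, n = 3), and EGFR from 37.01 ± 3.15 to 20 ± 3.33 FPKM (SD, n = 3).

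Another 3 lists passed in U87TR, but each was lost when a certain single library was left out. Of 25 glycolysis and hypoxia genes, 4 rose and 1 fell (7 and 1 adjusted over the list alone), with adjusted p = 0.00495, but adjusted p = 0.88 with an estimated correlation. That p rested on single parental libraries both ways, with 0.183 without U87MG replicate 1 and 3.92e-10 without U87MG replicate 3. Of 22 cholesterol synthesis genes, 3 rose (3 adjusted over the list alone), with adjusted p = 0.0314, but adjusted p = 0.88 with an estimated correlation, 0.0588 without U87MG replicate 1 and 0.0592 without U87TR replicate 3. Of 5 cancer-testis genes, 3 fell and 1 rose (the same adjusted over the list alone), with adjusted p = 0.0336, but adjusted p = 0.461 with an estimated correlation, 0.0576 with a replicate block and 0.0513 without U87MG replicate 3. MAGEA1 and MAGEA6 went from 12.48 ± 1.11 and 10.01 ± 0.358 FPKM (SD, n = 3) to 0 in every U87TR library, while MAGEC2 rose from 2.21 ± 0.202 to 12.38 ± 0.627 FPKM (SD, n = 3). NF-kB genes moved both ways in U87TR: IL1B fell from 116.4 ± 14.4 to 5.02 ± 1.23 FPKM (SD, n = 3) and BIRC3 rose from 3.167 ± 0.446 to 9 ± 0.653 FPKM (SD, n = 3), with 5 of 21 rising and 7 falling (adjusted p = 0.697).

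In U87TR 4294 genes changed, 1635 upward and 2659 downward, and 802 of them by at least 2-fold. The share that were higher was 38.1% on the deposited values, 52.3% with median-of-ratios factors, 46.2% after rescaling to TPM and 48.8% after quantile normalization. All 3 U87TR libraries come from another block of library codes than U87MG, so block and resistance cannot be told apart here. Other splits of the 6 U87 libraries passed as many as 10 lists, against 8 for the real split. Those splits also keep part of the real difference and do not show what chance alone gives.

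The series is titled for ferroptosis, an iron-dependent form of cell death through lipid peroxidation. GPX4, which codes for the enzyme that reduces lipid peroxides, showed no change that passed the test in either resistant line, with log2 fold changes of -0.08 (SE 0.08) in U251TR and -0.13 (SE 0.08) in U87TR. SLC7A11, the cystine transporter gene, had log2 fold changes of 0.03 (SE 0.28) and -0.27 (SE 0.28), which did not pass. Its U251MG libraries stood at 74.86, 32.97 and 83.69 FPKM, and the sign in U251TR turned with the U251MG library left out. The genes of ferritin, which stores iron, differed between the lines. FTH1 rose from 3176 ± 684 to 9164 ± 719 FPKM (SD, n = 3) in U251TR and was 8929 ± 1010 and 8615 ± 581 FPKM (SD, n = 3) in U87MG and U87TR. FTL rose 5.7-fold in U251TR, from 1937 ± 61.9 to 11060 ± 459 FPKM (SD, n = 3). NQO1 rose 3.79-fold in U251TR. AIFM2, which codes for the ubiquinone reductase FSP1, rose 3.07-fold in U251TR and 1.47-fold in U87TR. ACSL4 codes for an enzyme that links polyunsaturated fatty acids to coenzyme A. It fell by 0.7 on the log2 scale in U251TR (SE 0.13, adjusted p = 0.00052). In U87TR its log2 fold change was 0.06 (SE 0.13, adjusted p = 0.778). AKR1C1, AKR1C2 and AKR1C3 rose in both lines, by 24.1-, 15.9- and 8.87-fold in U251TR and by 5.32-, 2.01- and 3.99-fold in U87TR. SCD, the stearoyl-CoA desaturase gene, moved in opposite directions, from 186.6 ± 99.3 to 58.41 ± 3.83 FPKM (SD, n = 3) in U251TR and from 50.79 ± 27.7 to 152.6 ± 8.47 FPKM (SD, n = 3) in U87TR. HMOX1 did not pass in U251TR on all libraries (log2 fold change -0.25, SE 0.33) and did without U251MG replicate 2 (-0.78). TFRC, the transferrin receptor gene, was 0.24 higher in U251TR and 0.27 lower in U87TR on the log2 scale (SE 0.07 in both), but the U251TR call was lost in 4 other settings (adjusted p from 0.0524 to 0.122) and the U87TR call in 5 (adjusted p from 0.0699 to 0.0914), single libraries left out among them.

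Of 30 tested genes whose products counter ferroptosis, 18 rose and 3 fell in U251TR (18 and 4 adjusted over the list alone). Members shared with the NRF2 target list include NQO1, HMOX1, SLC7A11, AKR1C1, AKR1C2 and AKR1C3, so the results of these lists are not independent. The ferroptosis suppressor list passed at adjusted p = 0.0108, but not with an estimated correlation (adjusted p = 0.115) or without U251MG replicate 2 (adjusted p = 0.111). In U87TR 10 of its genes rose and 1 fell (10 and 5 adjusted over the list alone), and the list did not pass (adjusted p = 0.168). Its median log2 fold change there was -0.04 while its mean was 0.17 and its test pointed upward. The difference between the lines passed at adjusted p = 0.0455, but not with an estimated correlation (adjusted p = 0.263). That call was also lost with a replicate block (0.0531) and after rescaling to TPM (0.0538). It was lost as well without U251MG replicate 2 (0.229), U251TR replicate 3 (0.0695) or U87TR replicate 1 (0.0643). Of 32 genes whose products favour ferroptosis, 9 rose and 8 fell in U251TR (the same adjusted over the list alone) and 5 rose and 4 fell in U87TR (the same adjusted over the list alone). That list did not pass in either line (adjusted p = 0.381 and 0.32). SAT1 fell by 1.78 on the log2 scale in U251TR (SE 0.18), and ELOVL5 rose 1.49-fold in U87TR.

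The list of 21 repair genes that act on temozolomide lesions, MGMT among them, did not pass in either line. In U251TR 10 rose and 5 fell (the same adjusted over the list alone, adjusted p = 0.586). In U87TR MGMT was the only 1 that rose, and 6 fell (1 and 8 adjusted over the list alone, adjusted p = 0.876). PMS2, a mismatch repair gene, had a log2 fold change of -0.02 (SE 0.08) in U251TR. MSH6, another, fell by 0.41 on the log2 scale in U251TR (SE 0.14, adjusted p = 0.0237), a call that was lost without any 1 of 3 libraries and in 3 other settings (adjusted p from 0.0527 to 0.104). Neither passed in U87TR, where their log2 fold changes were 0.05 (SE 0.08) for PMS2 and 0.19 (SE 0.14) for MSH6. XRCC1, a scaffold of base excision repair, rose 1.82-fold in U251TR and fell by 0.47 on the log2 scale in U87TR.

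**Figure D2:**
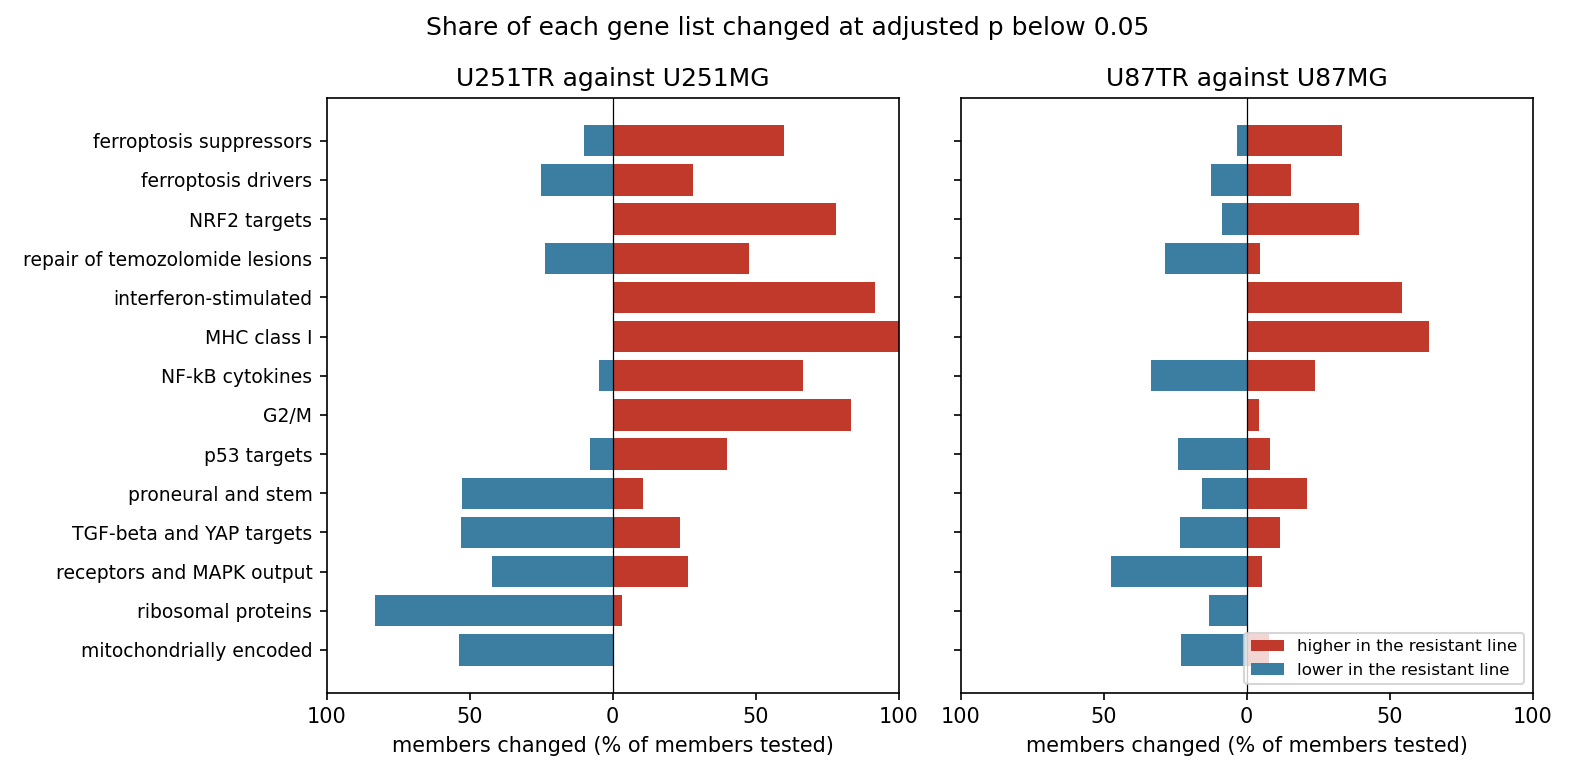
Share of the tested members of 14 gene lists that were higher (red, to the right) or lower (blue, to the left) in the resistant line at an adjusted p below 0.05, in percent of members tested, for U251TR against U251MG and U87TR against U87MG. Of 24 interferon-stimulated genes, 22 were higher in U251TR and 13 in U87TR; 25 of 30 ribosomal protein genes were lower in U251TR and 4 in U87TR.

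The third comparison asked which changes the resistant lines had in common. CCL5 and the interferon-stimulated genes IFIT2, RSAD2, IFIT1, IFIT3 and OASL were the 6 genes with the largest rises in both among genes at 10 FPKM or more on average in the higher group of each line, with log2 fold changes from 3.38 to 6.7 in U251TR and from 2.84 to 6.51 in U87TR. MGMT and SERPINA1 also rose in both and stood just under that limit in U251TR, at 8.67 ± 0.941 and 9.897 ± 1.51 FPKM (SD, n = 3). CCL5 was the one gene that went from under 0.5 FPKM in every parental library to 10 or more in every resistant library of both lines. CHI3L1 rose in both lines, in U87TR from 80.26 ± 9.48 to 486.6 ± 20.3 FPKM (SD, n = 3). Among the 6 largest shared falls under the same limit were HDAC9, MEST, PDP1, HOXB3 and FRMD4A, with log2 fold changes from -2.53 to -1.43 in U251TR and from -1.41 to -1.25 in U87TR. The sixth, MYEOV, fell by 3.64 on the log2 scale in U87TR (4.3 without U87TR replicate 3), while its fall of 1.54 in U251TR no longer passed with no filter (adjusted p = 0.0538) or without any 1 of 4 libraries (adjusted p = 0.0818 and 0.0866 without U251MG replicates 1 and 3, and 0.0617 and 0.077 without U251TR replicates 2 and 3). In all, 711 genes were higher in both lines, against 549.6 for independent lists, and 625 were lower in both, against 521.3. Of the genes changed by at least 2-fold, 99 were higher in both, against 34.9, and 31 were lower in both, against 18.5. Another 836 genes were higher in U251TR and lower in U87TR, against 893.8, and 238 the reverse, against 320.6. At 2-fold or more the opposite changes numbered 52, against 38.6, and 21, against 16.8, so they were fewer than for independent lists only when all changed genes were counted. Both comparisons use the same estimate of each gene's spread, so genes with little spread are more easily called in both. The figures for independent lists are therefore only a rough baseline. Across genes the fold changes of the lines were weakly correlated (Pearson r = 0.102, Spearman rho = 0.0895); genes are not independent replicates.

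**Figure D3:**
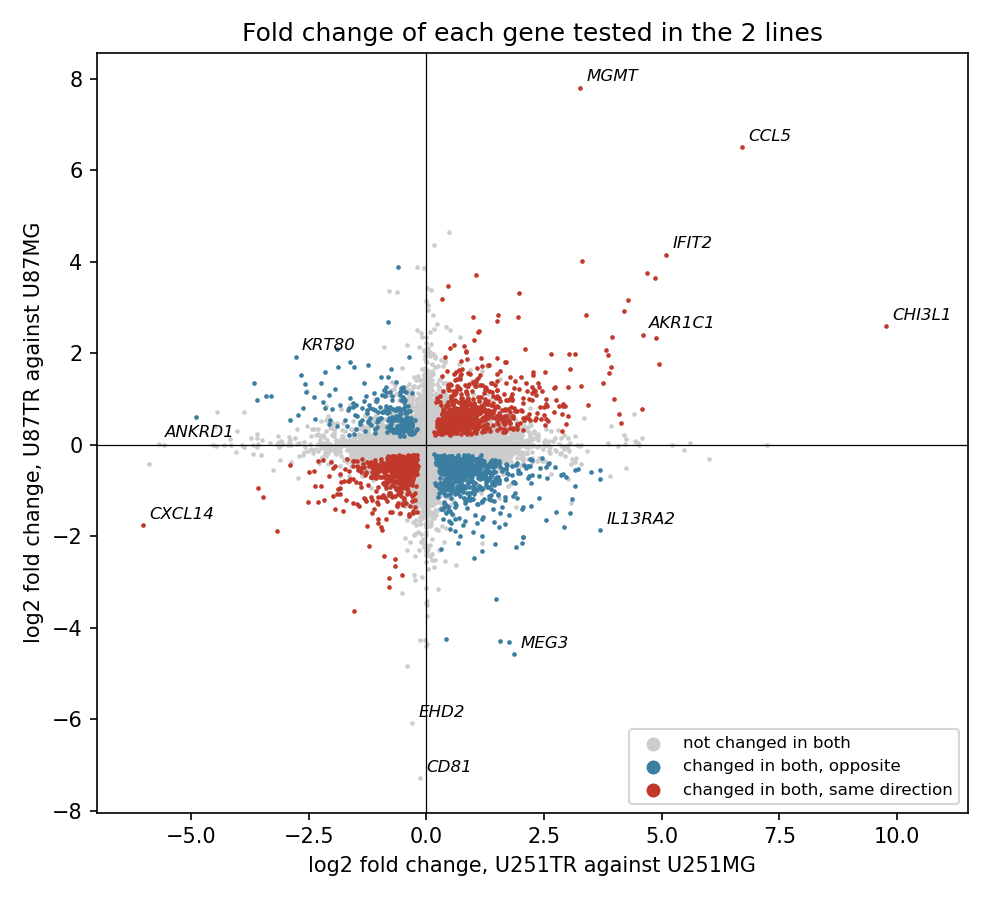
Log2 fold change of each of 15449 genes in U251TR against U251MG (horizontal axis) and U87TR against U87MG (vertical axis). Red points changed in both lines in the same direction, blue points changed in both in opposite directions, and grey points did not change in both; MGMT, CCL5 and IFIT2 lie at the upper right, and CD81 and EHD2 changed in U87TR but not in U251TR.

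The fourth comparison tested whether the change in U87TR differed from that in U251TR. It did for 7350 genes, 2384 with the larger value in U87TR and 4966 with the larger value in U251TR, and 2846 of them by at least 2-fold. Genes with opposite changes included IL13RA2, a receptor chain for interleukin 13, which rose 12.9-fold in U251TR and fell by 1.86 on the log2 scale in U87TR. KRT80, TUFT1, SEMA3B and NES went the other way, with falls in U251TR between 1.62 and 2.78 on the log2 scale and rises in U87TR between 3.03- and 4.31-fold. Interferon-stimulated genes had the larger rise in U251TR. At the threshold, the change in U87TR was below that in U251TR for 21 of 24 and above it for none. These counts were the same adjusted over the list alone. The list had adjusted p = 1.14e-05, but adjusted p = 0.119 with an estimated correlation. NF-kB genes also differed, with a lower change in U87TR for 16 of 21 and a higher one for 3 (the same adjusted over the list alone). That list had adjusted p = 0.00213, but adjusted p = 0.428 with an estimated correlation. CCL5 did not differ between the lines at the threshold (difference -0.19, SE 0.18, adjusted p = 0.401). None of the 11 lists that passed for the difference held with an estimated correlation. The share of these genes with the larger value in U87TR was 32.4%, against 47.0% with median-of-ratios factors, 27.9% after rescaling to TPM and 48.6% after quantile normalization.

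The parental lines themselves differed at 11170 of the 15449 genes, 4970 higher in U87MG and 6200 higher in U251MG, and 4884 by at least 2-fold. TFPI2, a protease inhibitor gene, had 1059 ± 149 FPKM (SD, n = 3) in U87MG and was listed at 0 in U251MG. COL6A3, MT1L, MIF and CSF3 were the next largest in U87MG among genes with a plain symbol, at 286.5 to 805.2 FPKM on average against at most 1.33 in U251MG. SOX2, a transcription factor of neural stem cells, had 219.8 ± 19.6 FPKM (SD, n = 3) in U251MG and was listed at 0 in U87MG. THY1, FABP7, GPM6A and SERPINF1 had between 214.0 and 818.6 FPKM on average in U251MG and under 1 in U87MG.

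Chromosome medians shifted in both resistant lines. Over 13632 tested genes with a chromosome, 19 of 23 chromosomes in U251TR and 11 of 23 in U87TR had a median fold change outside the central 95% of random gene sets of the same size. In U251TR the genes of chromosome X lay 0.327 below the median of all genes on the log2 scale, and those of chromosomes 1, 2, 7 and 15 lay 0.267, 0.23, 0.244 and 0.238 above it. In U87TR the largest shifts were those of chromosomes 18 and 11, which lay 0.202 and 0.189 below the median of all genes.

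**Figure D4:**
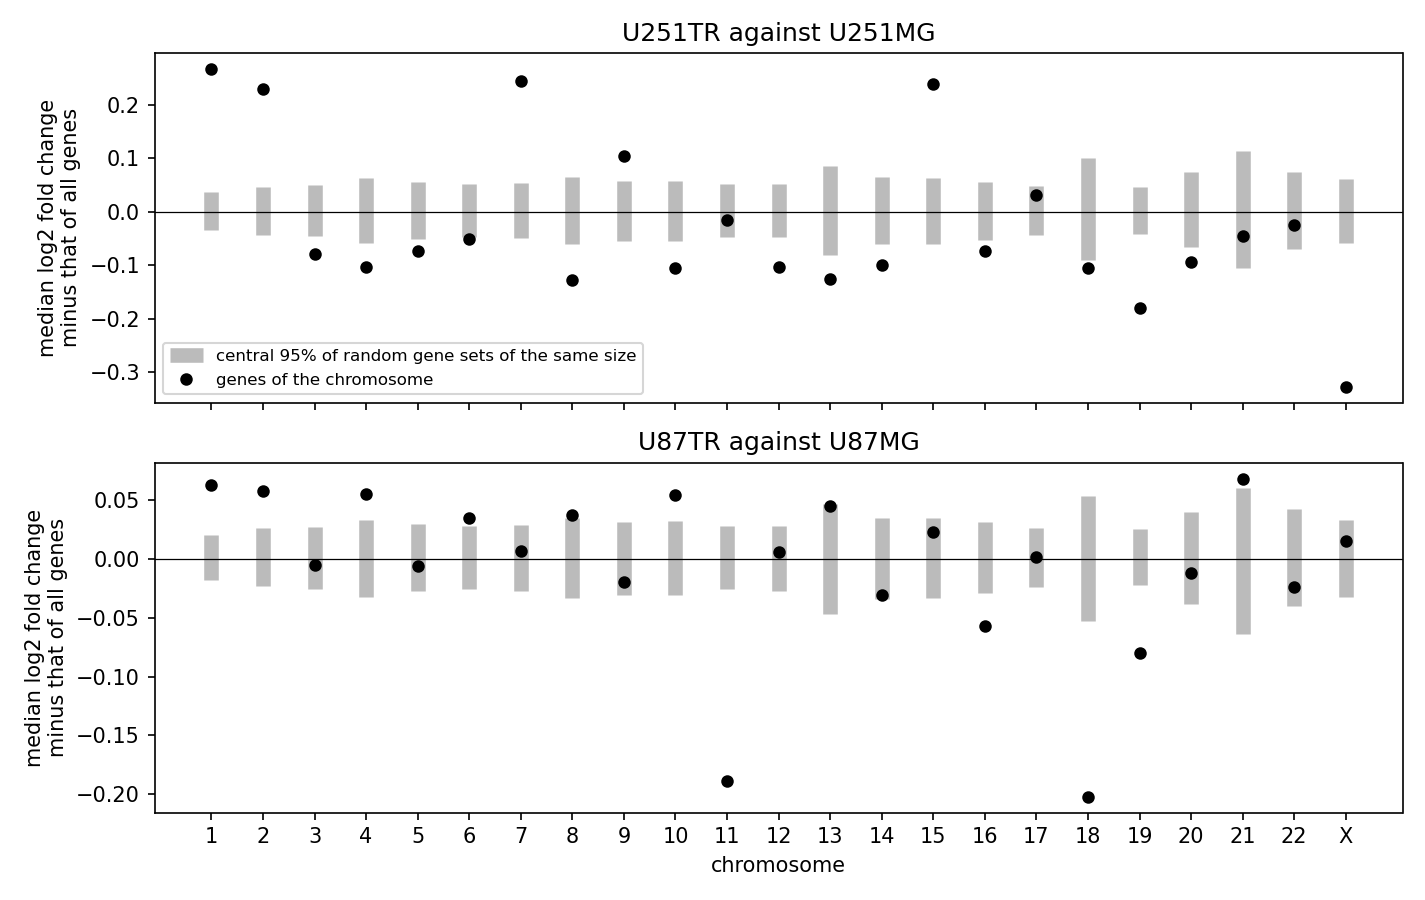
Median log2 fold change of the tested genes of each chromosome minus that of all genes (points), with the central 95% of 10000 random gene sets of the same size (grey bars), for U251TR against U251MG (top) and U87TR against U87MG (bottom). Chromosome X is lowest in U251TR, and chromosomes 11 and 18 are lowest in U87TR.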

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

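The tests of U87TR material in the U251TR libraries, of leukocytes, of the library block, and of another line as the source of U87TR were chosen only after the results were seen.

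MGMT was listed at 0 in all 6 parental libraries and was on in all 6 resistant libraries. U87TR material in the U251TR libraries would carry other U87TR genes along at the 3.87% that MGMT shows (U251TR mean over U87TR mean), but 17 genes high in U87TR and absent from U251MG had a median of 0.013% (2 of them were over 0.5 of the MGMT ratio), which argues against it. Copy gain of the MGMT neighbourhood would lift the 20 nearest tested genes, whose median log2 fold change was -0.12 in U87TR and 0.02 in U251TR, which argues against that as well. Gain of MGMT alone, with no change in its activity, would only multiply a transcript listed at 0 in all 6 parental libraries. The 7.7 to 9.58 FPKM in U251TR and 212.66 to 232.22 FPKM in U87TR argue against that, though copy number itself was not measured. Loss of promoter methylation and outgrowth of cells that already made MGMT could each give this pattern, and neither was tested here. In the U87 lines library block also stays open, because it cannot be told apart from resistance.

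Interferon-stimulated genes and CCL5 were higher in both resistant lines. Leukocytes in the resistant cultures would bring PTPRC, which reached at most 0.05 FPKM in the 6 resistant libraries, so they are not a likely source. Other blood markers did move: CD68, CD74, LAPTM5 and HLA-DRA rose in U251TR to means of at most 4.407 FPKM (4 of 4 tested, adjusted p = 0.0753 for the list), and CD68 rose in U87TR from 195.7 to 332 FPKM. Library code block is no explanation in the U251 lines, whose 6 libraries share a block and whose interferon list had a median log2 fold change of 2.51, but in the U87 lines (0.86) block and resistance cannot be told apart. Infection of a culture, drug still present at harvest, and a lasting response of the resistant cells could each raise these genes and were not tested.

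CD81, E2F7 and EHD2 were on in the 9 other libraries and off in all 3 U87TR libraries. Other processing of the U87TR block could remove single genes, and the count of 3 genes off in U87TR alone, against at most 2 for any other group, leaves that undecided. Complete loss of long chromosome segments in U87TR would switch off neighbours too, and 14.3% of the lost genes (1 of 7) had an adjacent gene also off, which argues against it as a general cause. That test used only neighbours at 5 FPKM or more in U87MG, so loss of a short segment stays open. CD81 lies in a run of 15 genes on chromosome 11, itself included, with a median log2 fold change of -0.56. Loss of some copies could lower such a run, but would leave transcript from the remaining copies. Means of 0.127 FPKM for CD81, 0.0133 for E2F7 and 0 for EHD2 in U87TR argue against it as the only cause. Origin of the U87TR libraries from another line is unlikely, because 98% of the U87MG genes stayed on.

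Groups were also set against other splits of the same libraries. A count as large as the real one came from 1 of 10 splits for the genes changed in U251TR, in U87TR and between the parental lines, which is the real split itself, and 10 splits are too few to go lower. The other splits gave at most 1, 1 and 2 genes. Each of them mixes the real groups, which puts the real difference into the spread. Low gene counts follow from that whenever the groups differ, so they are no measure of chance. For lists, 6 of 10 splits were as large in U251TR and 3 of 10 in U87TR. Mixed splits keep part of the real difference, so this does not decide whether chance could give list counts of this size. Of 100 splits within each line, 1 was as large for genes changed in both lines (1336 genes, the real one). The highest other split gave 1074, the number changed in opposite directions, because it mirrors the labels of one line and keeps the real groups. For the difference between the lines (7350 genes) it was 2, the other being that same mirrored split, with 7669 genes. Every remaining split mixes the real groups of at least 1 line, so its gene counts are no measure of chance either. For lists of the difference 7 of 100 splits were as large. Mixed splits keep part of the real changes here too, so whether chance could explain the count of 11 lists stays undecided.

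The change differed between the lines for 7350 genes. Lists with a different change, by adjusted p, were interferon-stimulated (1.14e-05), ribosomal protein (9.76e-07), epithelial marker (0.0012), NF-kB (0.00213), proneural and stem (0.00213), NRF2 target (0.00369), MHC class I (0.00369), G2 and mitosis (0.0053), glycolysis and hypoxia (0.0351), mitochondrially encoded (0.0351) and ferroptosis suppressor genes (0.0455). None of these passed with an estimated correlation (adjusted p = 0.119, 0.563, 0.225, 0.428, 0.263, 0.332, 0.549, 0.704, 0.819, 0.635 and 0.263 in the same order). The ribosomal protein call was also lost with quantile normalization (0.384). The glycolysis and hypoxia call was lost there (0.285), with median-of-ratios scaling (0.0755) and without any 1 of 4 libraries (0.054 to 0.163). The mitochondrially encoded call was lost without U251MG replicate 2 (0.0813) or U87MG replicate 3 (0.0576) and after rescaling to TPM (0.0538). The ferroptosis suppressor call was lost with a replicate block (0.0531) and after rescaling to TPM (0.0538). It was lost as well without U251MG replicate 2 (0.229), U251TR replicate 3 (0.0695) or U87TR replicate 1 (0.0643). The log2 change in U87TR exceeded that in U251TR by 0.76 for ACSL4, 0.6 for MSH6, 4.71 for KRT80, 4.01 for TUFT1, 3.43 for SEMA3B and 3.76 for NES. The same difference was -0.51 for TFRC, -1.6 for FTH1, -1.99 for NQO1, -1.06 for AIFM2, -1.54 for CDKN1A, -4.06 for CARD16 and -5.55 for IL13RA2. MGMT (4.54) and MEG3 (-6.45) were listed at 0 in a whole group, so the added 1 FPKM sets the size of their difference. GDF15 had a difference of -4.13, but its log2 fold change in U251TR was 1.9 on all libraries and 0.89 without U251MG replicate 2, its call there was lost in 4 settings, such as the fit on the 6 libraries alone (adjusted p = 0.0851), and its call in U87TR was lost without any 1 of 5 libraries (adjusted p from 0.0502 to 0.0757).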

How the results depend on the processing

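Calls of at least 2-fold numbered 2096 in U251TR, 802 in U87TR, 2846 for the difference, 130 in both lines in the same direction, and 4884 between the parental lines. Leaving out 1 library gave 7262 to 8961 genes in U251TR, 3013 to 4488 in U87TR, 6537 to 8425 for the difference, 945 to 1863 in both and 10529 to 11505 between parents. With a replicate block the counts were 8119, 4094, 7202, 1260 and 11137. Planned fits on counts were not run because the table holds no counts.

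Of 36 lists, 10, 8 and 11 passed in U251TR, in U87TR and for the difference. With an estimated correlation 1, 1 and 0 passed. Fry tests a list against no change, not against other genes, so its counts answer another question: 26, 18 and 22, and 36, 31 and 35 with its mixed test. Ferroptosis suppressors in U251TR had adjusted p = 0.115 with an estimated correlation, and 0.00443 to 0.111 with 1 library left out. For the difference they had 0.263 with an estimated correlation, 0.0531 with a replicate block, 0.0538 rescaled to TPM, and 0.0297 to 0.229 with 1 library left out. In U87TR they had 0.00179 with fry and 7.89e-09 mixed. Ferroptosis drivers had 1.72e-08 mixed in U251TR, 0.000331 with fry and 1.05e-07 mixed in U87TR, and 0.00231 and 1.62e-07 for the difference.

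Some list directions turned. With fry, whose direction is not relative to other genes, those that turned and had an adjusted p below 0.05 were mesenchymal (0.00244), astrocyte (0.0143), extracellular matrix (0.0245) and neuron genes (0.00183) in U251TR, temozolomide repair in U87TR (0.000104) and apoptosis genes for the difference (0.00209). With quantile normalization 2 calls turned and no longer passed: mitochondrially encoded transcripts in U251TR (0.851) and for the difference (0.783).

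Log2 fold changes of several fixed genes moved with the setting. In U251TR, MSH6 had -0.23 without U251MG replicate 2, TFRC had 0.13 with median-of-ratios scaling, PMS2 had 0.09 rescaled to TPM, and GPX4 had 0.03 rescaled to TPM and 0.02 after quantile normalization. HMOX1 had -0.78 without U251MG replicate 2 and 0.07 without U251MG replicate 1. SLC7A11 had -0.39 without U251MG replicate 2, 0.27 without U251MG replicate 3 and -0.08 with median-of-ratios scaling. In U87TR, ACSL4 had -0.04 without U87MG replicate 3 and 0.16 without U87MG replicate 1. FTH1 had -0.14 without U87MG replicate 3, 0.01 without U87MG replicate 1, 0.04 with median-of-ratios scaling and 0.14 after quantile normalization. NQO1 had 0.18 without U87MG replicate 1, -0.39 without U87MG replicate 3 and 0.02 with median-of-ratios scaling.

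With limits of 5 and 0.5, U251TR kept 88.9% of U251MG genes and 15.8% of U87MG genes, and U87TR kept 95.8% of U87MG genes and 1.73% of U251MG genes. With the stricter filter 18 and 11 chromosomes lay outside the central 95% in U251TR and U87TR.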

Other observations

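Runs of neighbouring genes moved together. The scan that found them was chosen only after the results were seen. In U87TR, 83 tested genes from WDR74 to SF3B2 on chromosome 11 had a median log2 fold change of -0.97 relative to all genes, and 94.0% of them were on the lower side. The 93 genes from ZSCAN30 to PARD6G on chromosome 18 had a median of -0.71. The 15 genes from MRPL23 to NUP98 on chromosome 11, a stretch that holds CD81, had a median of -0.56, and the chromosome 18 run holds ST8SIA5. Genes from NUF2 to ANKRD45 (40) and from RGS8 to PHLDA3 (42) on chromosome 1 had medians of 0.6 and 0.58. In U251TR, 29 genes from CLDND1 to BBX on chromosome 3 had a median of -0.99, 16 genes from RSBN1L to SLC25A40 on chromosome 7 had a median of 0.87, and 3 runs on chromosome X had medians of -0.97, -0.91 and -0.89.

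IFNB1, which codes for interferon beta, was at 11.28, 8.51 and 12.46 FPKM in the U251TR libraries and at 0.35, 0 and 0.27 in U251MG, and was listed at 0 in all 6 U87 libraries. IFNL1, which codes for a type III interferon, was listed at 0 in all parental libraries, at 2.74, 2.78 and 2.05 FPKM in U251TR and at 1.01, 1.33 and 1.15 FPKM in U87TR. Both genes were chosen after their values were seen.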
